A study of Mus musculus with 6 samples.

How the data were processed

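Bulk RNA sequencing of cultured mouse bone marrow derived macrophages was analysed in 3 groups of 2 samples: untransduced, transduced with an adenovirus carrying GFP (empty vector), and transduced with an adenovirus carrying the HER2.eSPR payload. Groups and replicate numbers were taken from the sample titles, and days (5, 6 and 10) from the series' design text. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure the spread between these samples only, which may be technical. Per the labels, polyadenylated RNA was enriched with oligo(dT) beads, libraries were made with a NEBNext Ultra kit and sequenced as paired ends on an Illumina HiSeq. The submitters' processing notes name STAR 2.5.3a, DESeq2 and the genome build mm10. The counting method, the annotation and any filter are not given in the sources used here.

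The deposited table holds a normalised signal per gene, which is an estimated gene count divided by a size factor per sample, per the file headers and the name that the submitters gave the table. The values are not raw counts. Of the low values (up to 20 steps) 77.3% to 79.7% per library were whole multiples, within a tolerance of 0.02, of a common step that stands for 1 read. The others were fractional, as when reads that fit several genes are split. Under the 95% needed, whole reads were not recovered, so count models (DESeq2, edgeR), planned for the case that they could be, were not run. The step gave size factors of 0.926 to 1.10 and estimated totals of 17445163 and 17384157 reads (untransduced), 17679413 and 17257472 (empty vector) and 16333824 and 16692291 (HER2.eSPR). These totals cover the listed genes only. The smallest sum over the 6 samples was 10.0 estimated reads, so genes below that total are not in the table. The 10 most abundant genes took 9.72% to 11.9% of the counts of a library. No pair of replicates was closer than sampling noise: the mean chi-square per gene within groups was 4.53, 3.14 and 3.70.

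Of the 16416 gene identifiers, 16402 are in GENCODE release M21 and 16286 have the same coordinates there. Coordinates are given 1-based on mm10 and cover whole genes. Of 14 symbols shared by 29 genes, the gene with the highest mean kept the symbol. All 6 per-sample columns were used. The kit is not stated to mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Genes of families with near-identical members (immunoglobulin constant genes, H2-Q and H2-T genes, Ifit, Oas, Gbp and Ifi200 genes, nuclear copies of mitochondrial genes) are uncertain where the authors' counting could split their reads.

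The following choices were made before the data were examined: groups, tests, gene lists, the rule for named genes and most alternatives. Values were analysed as log2(value + 1), where the pseudocount of 1 understates the change of low genes. Genes with a mean of at least 10 over the 6 samples were tested, 13245 in all. A linear model over all 6 samples, which share an estimate of the spread, was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a variance trend), and p-values were adjusted by Benjamini-Hochberg per comparison with a threshold of 0.05. Tests are two-sided. For a gene at 0 in every library of a group, the levels are given without a fold.

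Of 35 gene lists fixed beforehand, covering interferon, inflammatory, presentation, metabolic, stress and matrix genes, markers of other cell types and mitochondrial transcripts, 31 had at least 5 tested genes. They were tested with camera (preset correlation 0.01, adjusted over 31 lists), again with an estimated correlation, and with fry, which tests a list by itself. With an estimated correlation camera uses the residual degrees of freedom, which are few in 6 samples, so that setting has little power here. Counts of changed members are over all genes and, where stated, adjusted over the list alone. Named genes are the 8 largest rises and falls per comparison (adjusted p under 0.05, mean of at least 50, groups not overlapping, no clone or model names), the 3 members with the smallest p of each called list, at most 2 called members of each other list, and Erbb2 and Fcer1g. Genes outside this rule are named as such. Results of some genes that the rule takes are not reported here.

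The steps were tested on simulated data for the comparison of the vector groups, with 200 genes changed among 13220 tested: 86.6% of 67 genes changed 1.5-fold were recovered, 100% of 67 changed 2-fold and 100% of 66 changed 4-fold, and 13 of 204 calls were false (6.4%). The simulation gave every gene the same spread beyond counting noise and changed only genes with a mean of at least 50 in the vector groups. These rates need not hold for the real data, where the calls between the vector groups depended on the variance trend (below). In the real data the median standard error of a log2 fold change was 0.104. Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of 50, trimmed mean rescaling, quantile normalisation, no or a robust variance trend, only the 4 samples compared, the replicate number as a block, a 2-fold minimum and leaving out each library. A correction for exon length (union of exons, 13237 genes) was added after the data were seen, as was trimmed mean rescaling of the list tests. Scaling moved the median log2 fold change of all tested genes to at most 0.009 from 0. Comparisons with shared controls were set against 100 simulated draws of unchanged groups. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.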

Results

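RNA was sequenced from cultured macrophages of C57BL/6 mice that had been differentiated from bone marrow cells in vitro. The cells were replated on day 5 and handled on day 6 in 1 of 3 ways: left without virus (untransduced), given an adenovirus that carried green fluorescent protein (the empty vector), or given an adenovirus with a payload directed at HER2 (HER2.eSPR). HER2 is a receptor tyrosine kinase of epithelial tumours that is used as a target of engineered immune cells, and its mouse gene is Erbb2. RNA was collected on day 10 from 2 samples of each group, 6 in all. The table lists 16416 genes with normalised counts. The estimated number of reads behind each library ran from 16333824 (HER2.eSPR replicate 1) to 17679413 (empty vector replicate 1), so depth was similar in all 6. Replicates of a group correlated across genes with Pearson's r of 0.991, 0.991 and 0.991 on the log2 scale. Genes are not independent replicates, and these values describe the libraries only.

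The 3 comparisons ask what transduction with the GFP vector changed, what transduction with the HER2.eSPR vector changed, and how the vector groups differed from each other. Values below are mean normalised counts ± SD (n = 2 per group), and differences are log2 fold changes ± SE on the log2(value + 1) scale with limma's adjusted p over 13245 tested genes. Erbb2 (chromosome 11, 98412470 to 98437716, mm10) was listed at 9.1 and 10.0 in the untransduced libraries, 0 and 2.0 with the empty vector, and 3.2 and 2.1 with HER2.eSPR. That lies under the filter of a mean of 10, so Erbb2 was not tested. Fcer1g (chromosome 1, 171229572 to 171234365), the signalling chain shared by several Fc receptors, had 7969 ± 3.6 untransduced, 12349 ± 332.8 with the empty vector and 12315 ± 23.6 with HER2.eSPR.

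In macrophage cultures given the empty vector, interferon-stimulated and inflammatory genes were far higher than in untransduced cultures. Cell cycle, cholesterol synthesis and stromal genes were far lower. All 45 tested type I interferon-stimulated genes rose, with a median log2 fold change of 4.08. All 40 cell cycle genes fell (median -3.34), as did all 24 cholesterol synthesis genes (median -1.94). The change was broad: 4301 of 13245 genes were higher and 4213 lower, 64.3% of those tested. At least 2-fold changes were found for 1378 higher and 1642 lower genes, and at least 8-fold changes for 324 and 353.

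The genes with the largest rises held acute-phase, receptor and metabolic genes. Saa3, an acute-phase serum amyloid, went from 3.18 to 13443 (11.90 ± 0.34, adjusted p = 3.2e-13). Fpr1, a receptor for formylated bacterial peptides, rose by 11.72 ± 0.20, and the dicarboxylate transporter Slc13a3 by 11.49 ± 0.06 to a level of 46245. The scavenger receptor Marco rose by 10.60 ± 0.27, complement factor B (Cfb) by 9.50 ± 0.15, and Acod1, which makes itaconate, by 9.38 ± 0.07 (adjusted p = 2.0e-19). The immunoglobulin heavy chain constant genes Ighg2c and Ighg2b were listed at 0 in both untransduced libraries. Ighg2c (chromosome 12, 113285325 to 113288932) reached 7254 and 7179 in the empty vector libraries, and Ighg2b 965.0 and 984.3. The largest falls were in Nptx1 and Fbln2, both listed at 0 in each empty vector library against 271.6 and 268.0 untransduced. Next came fibronectin Fn1 (chromosome 1, 71585520 to 71653200; -7.58 ± 0.16), the type I collagen chains Col1a2 (-7.53 ± 0.39) and Col1a1 (-6.42 ± 0.31), the transporter Slco2b1 (-7.15 ± 0.65), the spindle gene Aspm (-6.66 ± 0.33) and the Ras exchange factor Rasgrp3 (-6.44 ± 0.35).

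Among interferon genes, Oas3 rose from 508.1 to 20079 (5.30 ± 0.06, adjusted p = 1.7e-17), Ifit3b by 7.98 ± 0.09 and the nucleic acid sensor Zbp1 by 6.61 ± 0.08. All 19 tested interferon-gamma-induced GTPases and regulators rose (median 4.85), with Igtp at 4.67 ± 0.06, Irgm1 at 3.51 ± 0.05 and Gbp6 at 7.46 ± 0.11. The interferon gene Ifnb1, the only listed member of the interferon ligand list, was at 0 in both untransduced libraries and at 28.7 and 41.6 with the empty vector. Of 29 genes for sensing of virus in the cytosol and endosome, 24 rose and 3 fell (median 1.15), led by Ifi205 (7.69 ± 0.12), Mndal (3.39 ± 0.07) and Samhd1 (2.29 ± 0.05). The members that fell, named after their values were seen, were Tmem173 (-0.50), which encodes STING, Tlr13 (-0.22) and Dnase2a (-1.05). Camera, limma's test of a list against the other genes, called these lists with adjusted p = 2.1e-30, 9.4e-15 and 1.3e-08. With an estimated correlation the calls were lost, at adjusted p = 0.234 for the type I list, 0.229 for the GTPases and 0.17 for virus sensing.

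Antigen presentation genes went in opposite directions by class. Of 22 MHC class I genes, 20 rose (median 1.90, camera adjusted p = 5.0e-11, adjusted p = 0.234 with an estimated correlation), including H2-T22 (4.03 ± 0.06), H2-Q4 (3.61 ± 0.06) and H2-K1, which went from 13489 to 74891 (2.47 ± 0.05). The 2 that fell, named after their values were seen, were the chaperones Calr (-1.26) and Pdia3 (-0.60). Of 10 MHC class II genes, 7 fell and 1 rose (median -1.48, camera adjusted p = 0.00478, adjusted p = 0.17 with an estimated correlation). Cd74, the invariant chain, fell by 2.36 ± 0.06, H2-Aa by 2.56 ± 0.12 and H2-Eb1 by 2.89 ± 0.15. The riser, named after its value was seen, was the protease gene Ctss (0.38 ± 0.04), a call lost after quantile normalisation (0.02, adjusted p = 0.589), which left 8 lower and 0 higher. Co-stimulatory and checkpoint ligands rose in 10 and fell in 3 of 16 cases (median 1.54, camera adjusted p = 0.00575, adjusted p = 0.285 with an estimated correlation). Cd274, which encodes PD-L1, rose by 3.83 ± 0.05, Siglec1 by 2.24 ± 0.05 and Tnfsf10, which encodes TRAIL, by 6.07 ± 0.15. The 3 that fell, named after their values were seen, were Havcr2 (-1.14), which encodes TIM-3, Cd83 (-1.04) and Tnfsf9 (-0.56).

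Inflammatory mediators of the NF-kB list rose in 24 and fell in 2 of 27 cases (median 2.40, camera adjusted p = 6.6e-11, adjusted p = 0.112 with an estimated correlation). Nfkbiz rose by 5.84 ± 0.06 and the adhesion molecule gene Icam1 by 2.40 ± 0.04. The 2 that fell, named after their values were seen, were Malt1 (-1.84) and Egr1 (-1.97). Chemokine genes went both ways, 10 higher and 5 lower of 16 (6 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.0677). Cxcl10 rose by 6.23 ± 0.10 and Ccl5 by 6.36 ± 0.12. Genes of the IL-4 type of activation fell in 11 and rose in 1 of 15 cases (median -1.26, camera adjusted p = 4.6e-04, adjusted p = 0.168 with an estimated correlation). Itgax, which encodes CD11c, fell by 4.32 ± 0.07 and the mannose receptor gene Mrc1 by 2.49 ± 0.05, and the riser, named after its value was seen, was the receptor gene Il4ra (2.05 ± 0.05).

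Macrophage identity genes went both ways, with 14 of 24 higher and 9 lower (median 0.25), but 11 higher and 11 lower after quantile normalisation (median -0.04). Camera did not call the list against the other genes (adjusted p = 0.131), and fry, which tests it by itself, did (adjusted p = 1.4e-04). Adgre1, which encodes F4/80, rose by 2.15 ± 0.05 from 15330 to 68247, and Aif1 by 3.46 ± 0.09. Fc and phagocytic receptors were split, 9 higher and 11 lower of 23 (9 and 13 after quantile normalisation, camera adjusted p = 0.838), with Fcgr1, a high-affinity receptor for IgG, at 2.73 ± 0.07 and Fcgr4 at an adjusted p of 8.9e-14. Genes of the interleukin-10 and glucocorticoid type were split likewise, 9 higher and 10 lower of 22 (9 and 12 after quantile normalisation, camera adjusted p = 0.969), with Spp1, which encodes osteopontin, at -1.83 ± 0.04 and Stab1 going from 21655 to 3813. Chains commonly built into synthetic receptors rose in 10 and fell in 4 of 16 cases (median 0.71, camera adjusted p = 0.0329, adjusted p = 0.418 with an estimated correlation). That call was also lost after quantile normalisation (adjusted p = 0.059). Cd28 fell by 3.07 ± 0.08 and Syk rose by 1.28 ± 0.04, and the others that fell, named after their values were seen, were Fcgr3 (-1.20), Ifngr1 (-0.46) and Tyrobp (-0.44). Of 11 genes of the adenovirus entry list, 3 were higher and 4 lower (4 and 5 after quantile normalisation, camera adjusted p = 0.984). Among them were Marco, given above, and the integrin gene Itgb5 at -1.31 ± 0.05.

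Proliferation genes fell throughout, with Mki67 going from 3721 to 226.8 (-4.03 ± 0.09, adjusted p = 3.3e-14), Top2a by -4.17 ± 0.11 and the ribonucleotide reductase gene Rrm1 by -2.84 ± 0.08. Camera gave adjusted p = 1.0e-20 for the cell cycle list (adjusted p = 0.112 with an estimated correlation) and 3.3e-14 for cholesterol synthesis (adjusted p = 0.0987 with an estimated correlation). In the latter, Insig1, a regulator of sterol synthesis, fell by 2.08 ± 0.06. LXR targets and lipid handling genes fell in 16 and rose in 5 of 23 cases, 17 lower when adjusted over the list alone (median -0.59, camera adjusted p = 0.00167, adjusted p = 0.17 with an estimated correlation). Scd2 fell by 2.56 ± 0.05, while Smpdl3a rose by 1.66 ± 0.04 and Nr1h3, which encodes LXR alpha, by 2.04 ± 0.05, and the other risers, named after their values were seen, were Ch25h (1.06), Mylip (0.90) and Abcg1 (0.47). Glycolysis and hypoxia genes fell in 18 and rose in 6 of 26 cases (median -0.68, camera adjusted p = 0.00271, adjusted p = 0.431 with an estimated correlation). Pdk1 fell by 2.84 ± 0.08, and Ndrg1 and Pfkfb3 rose by 2.75 ± 0.06 and 1.51 ± 0.05.

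Camera called no stress, lysosomal or immediate early list on the values as deposited. Of 21 p53 targets, 10 were higher and 3 lower (camera adjusted p = 0.0559), with Cdkn1a at 1.37 ± 0.05 and Sesn2 at 1.13 ± 0.06. Of 25 unfolded protein and integrated stress response genes, 6 were higher and 14 lower, 7 higher when adjusted over the list alone (camera adjusted p = 0.0588, and 0.0236 after quantile normalisation, which makes it a call), with Ddit3 at 2.61 ± 0.08 and Hsp90b1 at -1.14 ± 0.04. NRF2 targets had 9 higher and 8 lower of 22 (8 and 11 after quantile normalisation, camera adjusted p = 0.966), with Sqstm1 at 1.19 ± 0.05 and Prdx1 at -1.13 ± 0.05. Lysosomal genes had 10 higher and 14 lower of 26, 15 lower when adjusted over the list alone (camera adjusted p = 0.355, and a call at 0.0231 after quantile normalisation, with 6 higher and 16 lower), with Lgmn at 1.16 ± 0.04 and Atp6v0d2 at -2.45 ± 0.07. Of 21 immediate early genes, 10 were higher and 5 lower (camera adjusted p = 0.214), with Klf6 at 1.28 ± 0.04 and Egr2 at -4.52 ± 0.22.

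Extracellular matrix genes fell together with markers of stromal cells. Of 23 matrix genes, 17 fell and 5 rose (median -1.83, camera adjusted p = 5.1e-04, adjusted p = 0.17 with an estimated correlation), with the protease gene Plau at -3.64 ± 0.06 and Mmp14, among the risers, at 3.70 ± 0.07. The other risers, named after their values were seen, were Thbs1 (2.02), Tgm2 (1.73), Mmp8 (1.27) and Mmp13 (0.82). All 13 tested markers of fibroblasts and stroma fell (median -5.05, camera adjusted p = 5.4e-06, adjusted p = 0.112 with an estimated correlation). Col1a1 went from 904.8 ± 7.8 to 10.5 ± 6.2, Col1a2 from 961.8 ± 22.7 to 5.0 ± 4.2, and Col5a1 fell by 6.36 ± 0.40. The median marker kept 1.16% of its untransduced level. In RNA of whole cultures, a loss of stromal cells cannot be told apart from lower expression within cells.

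Other markers of cell types that a marrow culture can hold moved in part. Of 5 neutrophil genes 4 rose, among them Lcn2 (6.77 ± 0.49) and Csf3r (1.07 ± 0.08), and the list was not called (camera adjusted p = 0.0578), but was after quantile normalisation (0.0389). B lineage genes rose in 4 and fell in 1 of 6 cases, 5 higher when adjusted over the list alone (camera adjusted p = 0.19), with Cd22 at 1.32 ± 0.07 and Ighm at -1.50 ± 0.09. Dendritic cell genes had 1 higher and 3 lower of 7 (camera adjusted p = 0.12), among them Cst3 (-0.75 ± 0.04). Monocyte genes had 2 higher and 5 lower of 11 (camera adjusted p = 0.212), with Ms4a4c at 7.42 ± 0.12. Osteoclast genes had 4 higher and 6 lower of 12 (camera adjusted p = 0.352), with Acp5 at 2.52 ± 0.08. Lists with under 5 tested genes got no list test: 1 of 3 T and NK cell genes fell (Il7r, -0.92 ± 0.06), 1 of 3 mast cell and basophil genes rose and 2 fell (Csf1, -1.21 ± 0.11, and Kit, -3.49 ± 0.45, with Hdc, named after its value was seen, at 2.69 ± 0.42), and 1 of 4 erythroid and megakaryocytic genes fell (Treml1, -1.86 ± 0.38). Mitochondrially encoded transcripts, a measure of RNA quality among other things, fell in 12 and rose in 2 of 15 cases, 13 lower when adjusted over the list alone (median -1.18, camera adjusted p = 8.7e-05, adjusted p = 0.285 with an estimated correlation). Their share of all counts was 1.17% and 1.03% in the untransduced libraries and 0.66% and 0.64% with the empty vector. The ribosomal RNA mt-Rnr1 rose by 2.05 ± 0.05, as did mt-Rnr2, named after its value was seen (0.89 ± 0.07), while mt-Cytb fell by 1.88 ± 0.06. For every list of this comparison not given a separate value, the counts adjusted over the list alone equalled those over all genes.

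For some of the lists that were not called, further called members of the rising side, the falling side or both are given here. They were named after their values were seen unless given above. The chemokine genes that fell were Cxcl14 (-2.46), Cx3cl1 (-1.75), Ccl6 (-1.61), Ccl9 (-0.93) and Ccl2 (-0.47). Of the adenovirus entry list, in which F10 is not a receptor gene, Scarf1 (1.73) and Cd86 (1.59) rose beside Marco. F10 (-2.26), Itgb3 (-2.18) and Itgb1 (-0.27) fell beside Itgb5. The p53 targets that fell were Sesn1 (-1.18), Gtse1 (-0.89) and Gadd45a (-0.18), and the immediate early genes that fell beside Egr2 were Egr3 (-3.86), Egr1 (-1.97), Ier2 (-0.85) and Myc (-0.43). Neutrophil genes that rose beside Lcn2 and Csf3r were Padi4 (1.57) and Mmp8 (1.27), and B lineage genes that rose beside Cd22 were Igkc (2.87), Cd79b (2.56) and Ms4a1 (2.02). Of the dendritic cell genes, Xcr1 (2.48) rose, and Itgax and Kit fell beside Cst3. Of the monocyte genes, F13a1 (-3.83), S100a4 (-3.54), Ccr2 (-1.86) and S100a6 (-1.64) fell beside Fn1. The osteoclast genes that rose beside Acp5 were Ocstamp (1.31), Jdp2 (1.15) and Tnfrsf11a (0.69). Some calls of genes named after their values were seen were lost in other settings: Tnfsf9 after quantile normalisation (0.197), Ch25h without a variance trend (0.0515), and Gadd45a without a trend (0.17), without a filter (0.056) and once a trend on exon length was removed (0.0561). Tnfsf9 and Ch25h were also lost without any 1 of the 4 libraries compared (up to 0.141 and 0.154), Gadd45a without any of them but untransduced replicate 2 (up to 0.339), Ms4a1 without empty vector replicate 1 (0.0508) and Xcr1 without empty vector replicate 2 (0.0959).

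**Figure D1:**
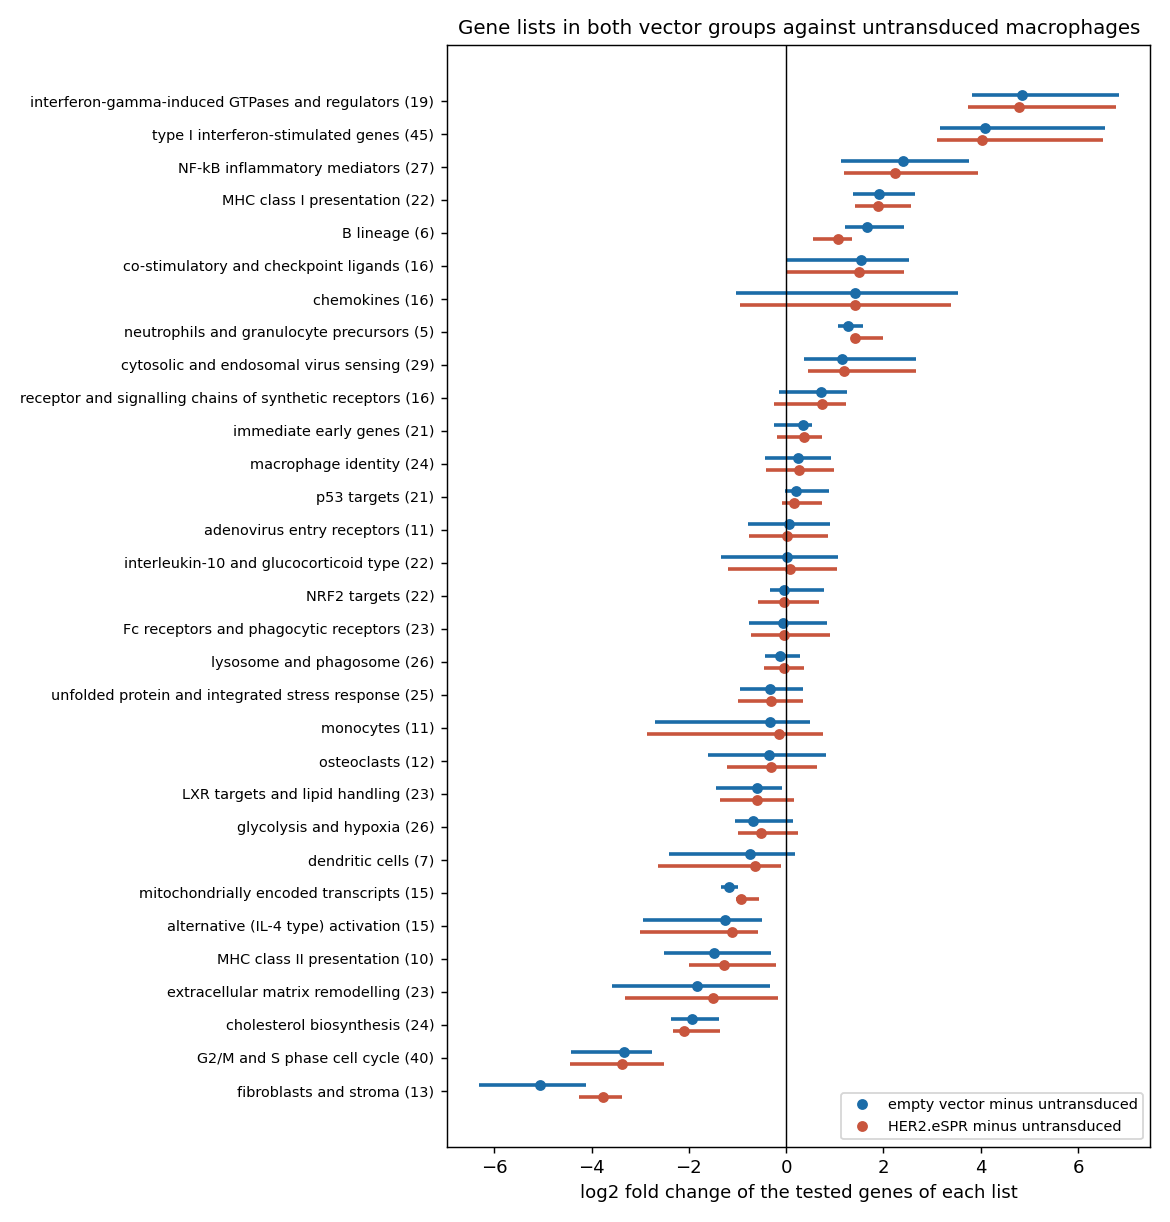
Median (point) and quartiles (line) of the log2 fold changes of the tested genes of each of 31 gene lists, with the number of genes in parentheses, for the empty vector (blue) and HER2.eSPR (red) against untransduced macrophages. Interferon lists lie highest, at medians of 4.85 and 4.08 with the empty vector, and stromal markers lowest, at -5.05 with the empty vector and -3.76 with HER2.eSPR.

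Macrophage cultures given the HER2.eSPR vector showed the same main groups against untransduced ones. All 45 type I interferon-stimulated genes rose (median 4.02), all 19 interferon-gamma-induced genes rose (median 4.78), all 40 cell cycle genes fell (median -3.38) and all 24 cholesterol synthesis genes fell (median -2.09). Ighg2c was at 8008 and 8355 and Ighg2b at 1176 and 1004, against 0 in both untransduced libraries. Saa3 rose by 11.88 ± 0.34, Fpr1 by 11.68 ± 0.20, Slc13a3 by 11.05 ± 0.06, Marco by 10.76 ± 0.27, Acod1 by 9.44 ± 0.07 and Cfb by 9.30 ± 0.15. In this comparison 4263 genes were higher and 4089 lower, 63.1% of those tested, with at least 2-fold changes in 1348 and 1544.

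The largest falls were in Nptx1 (from a mean of 271.6 to 0.53), Slco2b1 (-7.27 ± 0.65), the fatty acid desaturase gene Fads2 (-6.66 ± 0.25), Ankle1 (-6.42 ± 0.72), the helicase gene Pif1 (-6.17 ± 0.57), the phosphodiesterase gene Pde1c (-6.13 ± 0.64), and the mitotic genes Ube2c (-6.05 ± 0.33) and Ccnb2 (-6.04 ± 0.30). Oas3 rose by 5.22 ± 0.06, Igtp by 4.55 ± 0.06 and Ifi205 by 7.85 ± 0.12, and Ifnb1 was at 21.6 and 38.2. MHC class I genes rose in 20 of 22 cases (median 1.88) and MHC class II genes fell in 7 and rose in 2 of 10 (median -1.27), with Cd74 at -1.99 ± 0.06 and H2-Ab1 at -1.71 ± 0.10. The risers, named after their values were seen, were Ctss (0.41) and Ifi30 (0.13). After quantile normalisation both calls were lost, with Ctss at 0.04 (adjusted p = 0.255) and Ifi30 turned to -0.06 (0.276), which left 7 lower and 0 higher. The call of Ifi30 was also lost without a variance trend (0.0829), once a trend on exon length was removed (0.0851), and without any 1 of the 4 libraries compared (0.0618 to 0.113). Mki67 had -4.16 ± 0.09 and Insig1 -2.19 ± 0.06. Camera gave adjusted p = 7.6e-31 for type I interferon, 4.2e-15 for interferon-gamma, 3.3e-11 for MHC class I, 0.0165 for MHC class II, 1.4e-21 for the cell cycle and 8.6e-15 for cholesterol synthesis. With an estimated correlation these became adjusted p = 0.229, 0.223, 0.229, 0.223, 0.129 and 0.0928.

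Further lists were called in this comparison with adjusted p from camera, each followed here by the adjusted p with an estimated correlation. NF-kB mediators rose in 24 and fell in 2 of 27 cases (3.9e-11, then 0.129), and virus sensing genes rose in 24 and fell in 3 of 29 (5.8e-09, then 0.206). Co-stimulatory ligands rose in 10 and fell in 3 of 16 (0.00823, then 0.265). Chains of synthetic receptors rose in 10 and fell in 4 of 16, 5 lower when adjusted over the list alone (0.0397, then 0.462). The last call was lost after quantile normalisation (adjusted p = 0.0595) and without HER2.eSPR replicate 2 (adjusted p = 0.0502). IL-4 type genes fell in 11 and rose in 1 of 15 (8.3e-04, then 0.183). Unfolded protein and stress response genes fell in 15 and rose in 7 of 25 (0.0222, then 0.407), with Calr at -1.30 ± 0.05. LXR and lipid genes fell in 15 and rose in 6 of 23, 7 higher when adjusted over the list alone (0.00721, then 0.223). Glycolysis genes fell in 17 and rose in 7 of 26, 8 higher when adjusted over the list alone (0.00996, then 0.503). Matrix genes fell in 17 and rose in 5 of 23 (0.00199, then 0.223), beside stromal markers that fell in 13 of 13 cases (median -3.76; 5.4e-05, then 0.15) and kept a median of 6.65% of their untransduced level. Mitochondrially encoded transcripts fell in 12 and rose in 3 of 15 (0.00118, then 0.344), at 0.80% and 0.80% of counts. The other tested lists were not called, and their adjusted p-values were 0.0564 for chemokines (10 higher, 5 lower), 0.0712 for macrophage identity (14 and 8, but 11 and 12 after quantile normalisation, where the median of 0.27 became -0.04), 0.688 for interleukin-10 type genes (11 and 9, or 11 and 10 over the list alone, and 9 and 11 after quantile normalisation), 0.912 for phagocytic receptors (10 and 11, then 9 and 13), 0.894 for adenovirus entry (4 and 4, then 3 and 6), 0.0712 for p53 targets (10 and 2), 0.688 for NRF2 targets (8 and 9), 0.761 for lysosomal genes (9 and 11, then 6 and 15) and 0.146 for immediate early genes (11 and 5). Of other cell types, they were 0.0526 for neutrophils (4 and 0; 0.0393, a call, after quantile normalisation), 0.0647 for dendritic cells (1 and 3), 0.292 for monocytes (3 and 5), 0.455 for B lineage genes (3 and 1) and 0.39 for osteoclasts (4 and 6). Pf4, a platelet chemokine gene, rose by 0.39 ± 0.09 (adjusted p = 0.00205), a call lost after quantile normalisation (0.0678), without a variance trend (0.074) and without HER2.eSPR replicate 1 (0.0567). No list call in either comparison with untransduced cells held with an estimated correlation, 0 of 16 and 0 of 17. That estimate lay far above the preset 0.01 for type I interferon (0.711), interferon-gamma (0.529), MHC class I (0.397) and mitochondrial transcripts (0.312). For these lists the camera p-values at the preset assume less correlation between genes than was estimated. Calls were lost also where the estimate lay below the preset, as for cholesterol synthesis (-0.016) and stromal markers (-0.072). The test then has few degrees of freedom in 6 samples, so the losses cannot be put down to correlation between genes alone.

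Across the 13245 genes the log2 fold changes of the vector groups against untransduced cells correlated with Pearson's r = 0.977 and Spearman's rho = 0.956, and 91.8% had the same sign. These are correlations across genes, and both comparisons share the untransduced libraries. Simulated unchanged groups against those controls gave a mean r of 0.50, rho of 0.447 and 66.7% of the same sign over 100 draws. The covariance was 1.80 against 0.0252 in the simulation. With separate untransduced libraries as controls r was 0.948 and 0.944. Higher in both comparisons were 3897 genes, where independent lists would share 1384, and lower in both were 3740, where independent lists would share 1301. Unchanged groups simulated against the same controls shared 0.18 higher and 0.19 lower calls in the mean of 100 draws. That value leaves out the effects and the independent lists leave out the shared controls, so part of the excess may come from the shared controls. A single gene was called in opposite directions, a count of 1.

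**Figure D2:**
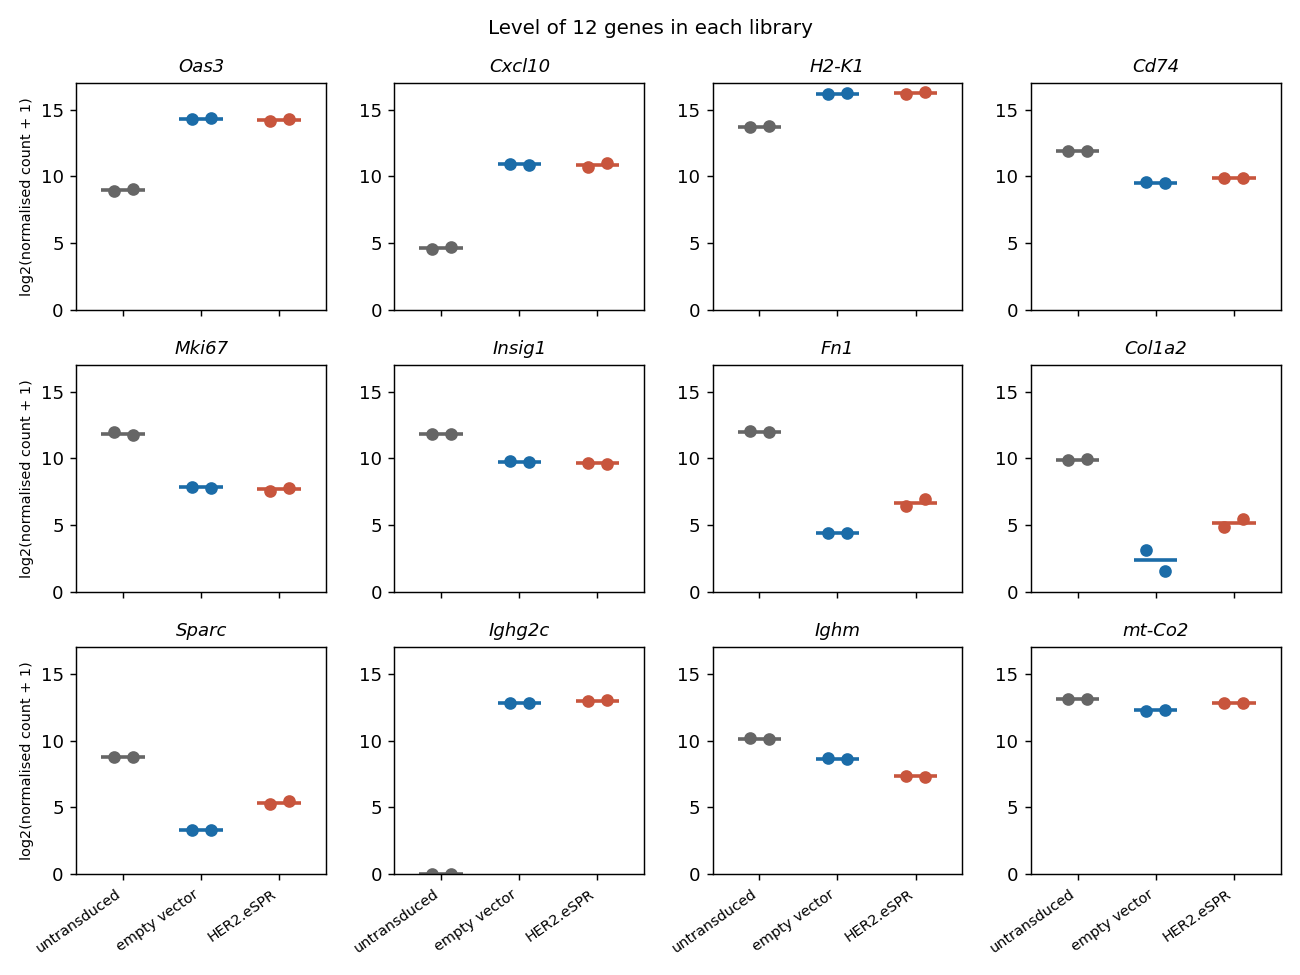
Normalised count of 12 genes in each of the 6 libraries on a log2(value + 1) axis; points are libraries and bars the mean of each group. Oas3 and Cxcl10 lie higher and Mki67 and Insig1 lower in both vector groups, Fn1, Col1a2 and Sparc lie between the others in the HER2.eSPR group, and Ighg2c is listed at 0 without virus.

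Between the vector groups the differences were few and mostly small: 80 genes were higher and 32 lower with HER2.eSPR, 0.8% of those tested, and 16 and 4 of them by at least 2-fold. The larger rises were in matrix and stromal genes. Fn1 went from 20.8 and 20.3 with the empty vector to 84.2 and 122.1 with HER2.eSPR (2.25 ± 0.16, adjusted p = 6.8e-06), against 4120 ± 199.8 untransduced. Col5a2 rose by 3.13 ± 0.41, Col1a2 by 2.79 ± 0.39, the collagen chaperone gene Serpinh1 by 2.71 ± 0.42, Col5a1 by 2.54 ± 0.40, tenascin Tnc by 2.41 ± 0.33 and Grem1 by 2.24 ± 0.42, with adjusted p between 0.00263 and 0.0238. Col1a2 was at 7.9 and 2.0 with the empty vector and 28.1 and 43.5 with HER2.eSPR. With the empty vector 0 of the 13 tested stromal markers reached a mean of 50, so their folds rest on low counts. Fbln2 was listed at 0 in both empty vector libraries and had 13.3 ± 6.7 with HER2.eSPR (8.6 in the lower library). Ighm fell by 1.34 ± 0.09 (adjusted p = 5.8e-06), from 403.5 ± 8.2 to 158.4 ± 1.9, and was at 1141 ± 66.4 untransduced.

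Other falls were in the lipid genes Scd1 (-1.21 ± 0.26) and Idi1 (-0.46 ± 0.09), in Sez6l2 (-0.59 ± 0.11), the nuclear RNA Malat1 (-0.50 ± 0.08), Slc13a3 (-0.45 ± 0.06) and the chemokine receptor gene Ccr3 (-0.44 ± 0.09), with adjusted p between 0.00299 and 0.0418. The falls named here are not the largest: the 2 genes that were at least 8-fold lower are not reported here. Of 23 matrix genes 5 rose, 12 when adjusted over the list alone (median 0.29, camera adjusted p = 4.1e-12, adjusted p = 0.112 with an estimated correlation). Among them were Fn1, Sparc (2.03 ± 0.23), Thbs1 (0.29 ± 0.05) and, named after its value was seen, Mmp14 (0.38 ± 0.07). The stromal markers moved with them: 3 of 13 rose (Col1a1, Col1a2 and Col5a1), 8 when adjusted over the list alone (median 1.09, camera adjusted p = 6.0e-09, adjusted p = 0.112 with an estimated correlation). Sparc was at 40.1 ± 4.8 with HER2.eSPR, 9.0 ± 0.2 with the empty vector and 435.5 ± 5.2 untransduced.

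Mitochondrially encoded transcripts rose in 7 of 15 cases, 10 higher and 1 lower when adjusted over the list alone (median 0.27, camera adjusted p = 4.1e-12, adjusted p = 0.168 with an estimated correlation), among them mt-Co2 (0.53 ± 0.04, adjusted p = 3.4e-05), mt-Co3 (0.44 ± 0.05) and mt-Cytb (0.35 ± 0.06). Fry did not call this list (adjusted p = 0.069). MHC class II genes rose in 2 of 10, 5 when adjusted over the list alone (camera adjusted p = 3.7e-06, adjusted p = 0.142 with an estimated correlation), Cd74 by 0.37 ± 0.06 and H2-Aa by 0.58 ± 0.12. Lysosomal genes rose in 3 of 26, 7 when adjusted over the list alone (camera adjusted p = 1.2e-06, adjusted p = 0.165 with an estimated correlation), with Ctsl at 0.24 ± 0.04, Atp6v0d2 at 0.32 ± 0.07 and Atp6v0c at 0.18 ± 0.04. Cholesterol synthesis genes fell in 2 of 24, 4 when adjusted over the list alone (median -0.10, camera adjusted p = 0.00171, adjusted p = 0.168 with an estimated correlation). B lineage genes fell in 1 of 6 (Ighm), 2 when adjusted over the list alone (median -0.96, camera adjusted p = 1.5e-04, adjusted p = 0.168 with an estimated correlation). Igkc, at 124.4 ± 32.4 with the empty vector and 42.3 ± 4.8 with HER2.eSPR, missed the threshold over all genes (-1.52 ± 0.33, adjusted p = 0.0531). It passed with a pseudocount of 5 (adjusted p = 0.0215), with a robust variance trend (0.0213), with the 4 samples alone (0.00459) and without untransduced replicate 1 (0.0086) or 2 (0.0116). Outside called lists, the fatty acid binding protein genes Fabp4 and Fabp5 rose by 0.61 ± 0.08 and 0.30 ± 0.05, the chemokine gene Ccl6 by 0.35 ± 0.05, Clec4e by 0.44 ± 0.10 and Fos by 0.36 ± 0.07.

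Smaller list shifts were also called by camera. Of 22 interleukin-10 type genes 1 rose (Trem2, 0.23 ± 0.04), 4 when adjusted over the list alone (adjusted p = 0.00445, adjusted p = 0.168 with an estimated correlation). Of 23 phagocytic receptors 3 rose (Fcgr3, 0.29 ± 0.05, Mfge8, 0.25 ± 0.05, and Clec7a, 0.20 ± 0.04), and adjusted over the list alone also 3. Of 15 IL-4 type genes 2 rose (Fn1 and Clec7a), 3 when adjusted over the list alone. Of 24 identity genes 2 rose (among them Trem2), 3 higher and 1 lower when adjusted over the list alone. Each of these 3 lists had adjusted p = 0.0149, and adjusted p = 0.174 with an estimated correlation. Their calls were lost without empty vector replicate 1 (adjusted p = 0.0614, 0.116 and 0.114) and without HER2.eSPR replicate 1 (0.0523, 0.11 and 0.0523), and that of the identity genes also after quantile normalisation (0.192) and once a trend on exon length was removed (0.0652).

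No member of the 3 remaining called lists passed the test by itself, over all genes or adjusted over the list alone (0 of 26, 0 of 25 and 0 of 45). Glycolysis genes lay higher (median 0.10, camera adjusted p = 0.0012, adjusted p = 0.518 with an estimated correlation), and the call was lost without HER2.eSPR replicate 1 (adjusted p = 0.0523). Stress response genes lay lower (median -0.05, adjusted p = 0.011, adjusted p = 0.475 with an estimated correlation), and the call was lost without HER2.eSPR replicate 2 (adjusted p = 0.0993). Type I interferon-stimulated genes lay lower (median -0.06, adjusted p = 0.00555, adjusted p = 0.791 with an estimated correlation), with Herc6 at -0.17 ± 0.06. That call was lost without empty vector replicate 2 (adjusted p = 0.0944), and without HER2.eSPR replicate 1 the direction turned (adjusted p = 0.70). No list call between the vector groups held with an estimated correlation, 0 of 14, a setting with little power in 6 samples. Interferon-gamma genes (adjusted p = 0.452), MHC class I genes (0.834), NF-kB mediators (0.973), virus sensing genes (0.833) and cell cycle genes (0.563) were not called between the vector groups. Nor were co-stimulatory ligands (0.833), chemokines (0.451), synthetic receptor chains (0.525), adenovirus entry genes (0.312) and p53 targets (0.555). The same held for NRF2 targets (0.122, but 0.02 after quantile normalisation), LXR targets (0.298) and immediate early genes (0.091). Markers of neutrophils (0.296), dendritic cells (0.834), monocytes (0.122) and osteoclasts (0.0697) were not called either.

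The count of genes between the vector groups depended on single libraries. Against 80 higher and 32 lower in all, 18 calls were made without empty vector replicate 1, 20 without empty vector replicate 2, 20 without HER2.eSPR replicate 1 and 6 without HER2.eSPR replicate 2, and 231 and 230 without untransduced replicates 1 and 2, and limma without a variance trend made 0 calls (1274 genes at an unadjusted p under 0.05, against 1603 with the trend). The genes that passed without any 1 of the 6 libraries were 5: Fn1, Ighm, mt-Co2, mt-Co3 and Gm10925 (0.53 ± 0.05, an unprocessed pseudogene on chromosome 1, 24613974 to 24614651), the last named after its values were seen. Reads counted for this pseudogene may come from a near-identical gene, such as a mitochondrial one, which was not tested. It may therefore not be a result separate from mt-Co2 and mt-Co3. Some of the named calls between the vector groups were also lost in other settings, each at a similar fold: with a robust variance trend Malat1 (adjusted p = 0.267) and Col1a2 (0.0643), and with the 4 samples alone Scd1 (0.174), Idi1 (0.112), H2-Aa (0.0624) and Col5a1 (0.0522). Without a filter, Scd1 (0.0802), Atp6v0d2 (0.0759), Clec7a (0.0721), Atp6v0c (0.0674), Clec4e (0.0658) and Mmp14 (0.0515) were lost. After quantile normalisation, Atp6v0c (0.0853), Clec4e (0.0847), Mfge8 (0.0822), Clec7a (0.0727), Atp6v0d2 (0.0727), Mmp14 (0.0676), Fos (0.0621), H2-Aa (0.0582), Scd1 (0.0569), Sez6l2 (0.0569) and Ccr3 (0.0507) were lost, and once a trend on exon length was removed, Atp6v0c (0.082), Clec7a (0.073), Clec4e (0.0604) and Atp6v0d2 (0.0576).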

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

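The correction for exon length and trimmed mean rescaling of the list tests were chosen only after the results were seen, and the other alternatives before. Against untransduced cells the numbers of higher and lower genes stayed within 1.5 times under every alternative run except the 2-fold minimum, which left 1378 and 1642 genes with the empty vector and 1348 and 1544 with HER2.eSPR. Between the vector groups (80 higher, 32 lower) that minimum left 16 and 4. There, quantile normalisation gave 49 and 21, no variance trend 0 and 0 (lowest adjusted p 0.0798, 1274 genes at an unadjusted p under 0.05), a robust trend 116 and 53, and the 4 samples alone 131 and 107 (55% higher, against 71.4%); the cause was not tested. The correction for exon length gave 68 and 23. Fitting the replicate number as a block gave 151 and 75 there, and 4358 and 4266, and 4320 and 4139, in the comparisons with untransduced cells. The correlations of same-numbered deviations were 0, -0.005 and 0.077, so no clear pairing by number was seen. A single difference per group cannot exclude it. Leaving out each library gave 4 to 140 higher and 1 to 91 lower genes between the vector groups; with a lone sample in a group, that sample is assumed to vary like the other groups. Of named genes, 1598 results kept their side of the threshold and 2 became weaker (empty vector against untransduced), 1684 and 7 (HER2.eSPR against untransduced), and 740 and 203 between the vector groups, where 26 became stronger and 2 reversed: Gpnmb and Lyz2 had a log2 fold change of 0 and 0 after quantile normalisation, because a gene of equal rank in both groups gets the same value. Between the vector groups the gene list type I interferon-stimulated genes, HER2_eSPR vs empty_vector, had, with a library left out, adjusted p-values from 5.9e-08 (without HER2.eSPR replicate 2) to 0.7 (without HER2.eSPR replicate 1, where its direction turned), and 0.791 with an estimated correlation and 0.82 with fry. The correlation across genes of the responses in the vector groups was 0.948 and 0.944 with separate controls. Of called lists, 0 of 16, 0 of 17 and 0 of 14 held with an estimated correlation, 16, 17 and 8 with fry, and 15, 16 and 13 after quantile normalisation. Besides the type I interferon list, fry lost between the vector groups mitochondrial transcripts (adjusted p = 0.069), macrophage identity (0.0854), IL-4 type (0.0896), stress response (0.174) and glycolysis genes (0.478). The estimated correlation leaves few degrees of freedom in 6 samples, so its losses cannot be put down to correlation between genes alone. Of 15, 14 and 17 lists that camera did not call, fry called 12, 11 and 0, quantile normalisation 3, 1 and 1, and the block 1, 2 and 1 (neutrophil genes at 0.0474 and 0.0392 against untransduced, chemokines at 0.0464 with HER2.eSPR, osteoclast genes at 0.0336 between the vector groups). With the block Igkc also passed between the vector groups (0.0246). Count models were not run, because whole reads were not recovered. Depth was similar in all 6 libraries and limits genes below a mean of 10, among them Erbb2.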

Other observations

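Of the tests below, those on carry-over of all cells, on immunoglobulin genes and on exon length were chosen only after the result was seen; the second stromal list and the slope were written down before their values were. In the next paragraph, Neat1 was chosen after its values were seen.

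The abundant nuclear RNAs Malat1 and Neat1 went in opposite directions. RNA was enriched with oligo(dT) beads and values are per gene, so these values do not measure single isoforms or transcripts without a poly(A) tail. Malat1 had 2416 and 2132 untransduced, 6039 and 6634 with the empty vector and 4014 and 4972 with HER2.eSPR, a rise of 1.48 (adjusted p = 8.7e-10) and 0.98 (1.1e-07) against untransduced cells and a difference of -0.50 between the vector groups (0.0132). The last call was lost at the same fold with a robust variance trend (0.267) and without a trend (0.449), and without empty vector replicate 1 (0.151), empty vector replicate 2 (0.286) or HER2.eSPR replicate 1 (0.173). Neat1, which scaffolds paraspeckles, had 18975 and 20016 untransduced, 10965 and 11626 with the empty vector and 14449 and 17787 with HER2.eSPR, a fall of -0.79 (1.8e-07) and -0.28 (0.00317) and a rise of 0.51 (0.0035) between the vector groups. That rise was lost without a variance trend (0.434), with a robust trend (0.209), and without empty vector replicate 1 (0.193), empty vector replicate 2 (0.105) or HER2.eSPR replicate 2 (0.0804), and the fall of -0.28 without a trend (0.102), with a robust trend (0.095) and without HER2.eSPR replicate 1 (0.0664). Fcer1g rose by 0.63 ± 0.04 with the empty vector (adjusted p = 2.4e-09) and by 0.63 with HER2.eSPR (2.7e-09), with 0.00 between the vector groups (0.983).

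Of 13 stromal markers, 12 were less reduced with HER2.eSPR than with the empty vector, as were Fn1 and Sparc. Only 3 of the markers passed the threshold over all genes, and the list call was lost with an estimated correlation (camera adjusted p = 0.112). Stromal cells left in the HER2.eSPR cultures are a candidate explanation. In a second list of stromal genes, 20 of 25 measured genes (80%) were higher with HER2.eSPR, which is exactly the bound of 80% set beforehand; 0 of them passed the test singly, 2 are in the fixed lists, and of 6 genes at 50 or more with the empty vector 3 were higher. Carry-over of untransduced cells of every type predicts that cell cycle genes lie higher by 0.49, if such cells keep their untransduced levels. Their median difference was -0.018 (interval -0.07 to 0.02, from resampling genes and not libraries). This argues against carry-over of cells that kept those levels. It cannot decide on cells that had stopped cycling in the vector cultures. Mmp14 and Thbs1, picked here after their values were seen, lay above untransduced (237.4 and 1703) with the empty vector (3093 and 6888) and higher still with HER2.eSPR (4020 and 8443). Leftover cells at untransduced levels would not raise them, which goes against such cells as the source of every difference in matrix genes. Both rises between the vector groups were lost without a variance trend (limma adjusted p = 0.453 and 0.434), so the argument is limited. An effect of the payload on expression was not tested and stays open.

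Ighg2c and Ighg2b were abundant in both vector groups and listed at 0 without virus. Antibody-producing cells would bring light chains, but Igkc, the kappa chain, reached at most 2.03% of Ighg2c. This argues against B lineage or plasma cells with kappa chains as the main source. Lambda chains were not examined. Some B lineage cells are not excluded: Igkc had a mean of 16.9 untransduced and 124.4 with the empty vector, and Cd79b 9.1 and 58.2, although Ighm fell. A shift of reads among the 5 listed heavy chain constant genes would leave their sum level, but the sum was 7.87 times higher with the vectors (1188 and 1103 untransduced, 8638 and 8566, and 9351 and 9519). Sequence carried by the vectors, which might be counted as these genes, was not tested, nor was a response of the macrophages, so both stay open.

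The differences between the vector groups were mostly small, with at least 2-fold changes in 16 higher and 4 lower genes and at least 8-fold changes in 3 and 2. Lower genes had longer exons (median 8415 bases) than higher ones (3612, with 4133 for all tested genes). Once a trend on exon length was removed, 86 of the calls stayed (76.8%), which argues against the trend as the whole cause, by a bound (75%) set when the value was known. The trend itself (Spearman's rho -0.087 across genes) was like that between replicates (-0.073, -0.084 and -0.043). A slightly weaker response to the vector with HER2.eSPR may account for part: the slopes against the empty vector response were 0.961 and 0.965, under the bound of 0.97 set beforehand, while replicates gave 0.996 to 1.013. The lists did not all weaken. With the empty vector and HER2.eSPR, the medians were -3.34 and -3.38 for cell cycle and -1.94 and -2.09 for cholesterol synthesis genes. They were 4.08 and 4.02 for type I interferon-stimulated genes and -1.48 and -1.27 for MHC class II genes. In checks added after that result, single libraries gave 0.955 to 0.971 and the slopes without matrix and stromal genes were 0.968 and 0.973, so they cross the bound; the reason for a weaker response, such as a lower dose of vector, was not measured.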
